A study of Homo sapiens with 12 samples.

How the data were processed

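The 12 libraries came from human induced neurons, made from the H1 human embryonic stem cell line by overexpressing the transcription factor Ngn2, per the labels. The cultures were either wild type at the LLPH locus (wt/wt) or homozygous for an allele that the labels call Nterm (Nterm/Nterm). What the Nterm allele changes in LLPH is not given in the sources used here. Per the labels' protocols, cells grew without added glia until day in vitro 14, with doxycycline at 2 µg/mL and cytosine arabinoside, which acts against dividing cells, at 4 µM in the medium exchanged on day 5 and in part on day 10. Per the labels' protocols, cells were detached with Accutase in cycloheximide at 100 µg/mL and cytoplasmic lysates were prepared. Ribo-seq libraries were made from ribosome footprints, the mRNA fragments left after digestion with RNase A and RNase T1 and isolation of ribosomes on sucrose gradients, per the labels. RNA-seq libraries were made from polyA RNA, per the labels.

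The deposited count table holds whole-number counts for 19972 transcripts, each under 1 Ensembl transcript identifier, in the 12 libraries. These counts were not normalised. Per the submitters' processing notes, which name tools with neither roles nor order, cutadapt 2.4, UMI-tools 1.0.1, Bowtie2 2.3.4.3, Salmon 1.4.0, edgeR and limma were used with genome build GRCh37. How reads that match several transcripts were counted is not given in the sources used here, so values of genes with close paralogs or pseudogenes, such as clustered protocadherins, ribosomal proteins and EEF1G, are uncertain. The deposited translational efficiency table gives, per the file headers, the mean ratio of footprints to RNA and its SD per genotype, and the ratio of the Nterm/Nterm mean to the wt/wt mean, for 10932 transcripts. The ratio equalled, within 1e-06, the quotient of the deposited means for 10932 transcripts. The deposited p-value is unadjusted, and it equalled, within 1e-06 for 10932 transcripts, a p recomputed from the deposited means and SDs with unequal variances and 3 libraries per genotype. A deposited column of 0 or 1 that marks ratios below 1 was not used here.

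Gene names came from the deposited translational efficiency table, which pairs transcript identifiers with names. This named 10873 transcripts, 1 of them through the gene name reference, and left 9099 without a name. Every transcript of that table had a total of at least 1016 counts, so the named transcripts are the better covered ones. A total of 1365 transcripts had no count in any library. Older gene symbols were matched through RefSeq gene names of assembly GRCh38.p14, from which no coordinates were taken.

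Samples were grouped by assay and by the genotype in the sample title and description, which gave 4 groups of 3 libraries. For 6 of the 12 samples, the Ribo-seq samples, the genotype tag names the opposite genotype to the title and description. Groups followed the titles, and the column names of the deposited counts name the same genotypes as the titles. The footprint fit, the translational efficiency fit and the correlation of RNA with footprint changes were also run with the tag, and the list tests were not. The series-level design text describes another experiment, so the questions were taken from the sample labels. Nothing in the labels says that replicates come from separate cultures or separate clones, so p-values measure only the spread between these samples.

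Transcripts were tested with edgeR 4.0.16 in R 4.3.3. Counts were scaled with TMM factors, low counts were removed with filterByExpr, and genotype was tested with the quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. RNA and footprint libraries were fitted separately. Translational efficiency, the footprint level relative to the RNA level, was tested as the interaction of assay and genotype over all 12 libraries, with TMM factors set within each assay. Such scaling removes a change shared by most transcripts, so the changes of each fit are relative to the other transcripts. Log2 changes are Nterm/Nterm minus wt/wt, as fitted by edgeR. Their standard error (SE) was derived as the size of the change divided by the square root of the F statistic. Counts scaled to library size (CPM) are given as mean and SD. For genes near 0 in 1 genotype, and for LLPH, the ratio of summed counts is given with a 95% interval that covers counting error only. These sums were scaled by library totals after the filter times the TMM factors. Counts of 10, 100 and 1000 carry counting errors of 31.6%, 10% and 3.16%.

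A total of 30 gene lists, with 1219 entries, was fixed before the data were examined, as were the grouping, the tests, the rule for named genes and most alternatives. The lists cover ribosomal proteins and other translation machinery, neuronal gene groups, markers of other cell types, stress responses, metabolism and RNA-quality controls. Of the entries, 1018 matched a named transcript. The 2 lists with fewer than 5 tested members, endoderm and mesoderm markers and mitochondrially encoded genes, were not tested. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the 28 lists of a fit, and again with the correlation estimated from the data and with fry. Counts adjusted over the list alone use the p-values of the members only.

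Named genes followed a rule. LLPH was named in every library. In each fit, the 10 largest increases and the 10 largest decreases were taken among genes past the threshold whose 2 genotypes did not overlap, with a symbol and a mean of at least 10 CPM in the higher group, or for translational efficiency a mean RNA level of at least 10 CPM. Overlap in translational efficiency was judged on log2 footprint CPM minus log2 RNA CPM of libraries with the same genotype and number. Of each described list, up to 4 members with the smallest p were taken. Genes named outside this rule are marked as chosen after their values were seen.

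The fits were tested on simulated counts drawn from the real means and library sizes, with 50 genes changed at each of 4 fold sizes. All transcripts of an assay were given the same spread, genes were drawn independently, and only transcripts with a mean over 50 counts were changed. Recovery and false calls may be worse in the real data, where spread differs between genes and genes are correlated. The RNA fit, run on 14545 simulated transcripts, recovered 56% of 1.25-fold, 98% of 1.5-fold and 100% of 2-fold changes, with 5.35% false calls. The footprint fit, run on 13546, recovered 52%, 90% and 98% at the same sizes, with 3.41% false calls. The translational efficiency fit, run on 14689, recovered 30%, 82% and 98%, with 6.63% false calls.

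Alternatives covered size factors of DESeq2, upper-quartile scaling, no filter, a filter of 10 counts in every library, the DESeq2 1.42.0 Wald test, limma-voom, a block for the replicate number, a block for libraries of 1 genotype and number, TMM over all libraries, footprint groups by the genotype tag, and each library left out in turn. Added after seeing the data were fits without the libraries numbered 3, fits of DESeq2 without its filter on the mean count, and the block fit without the wt/wt libraries numbered 2. The relation of translational efficiency to coding sequence length was not analysed here, since no coding lengths were available.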

Results

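The data cover human induced neurons of 2 genotypes at day in vitro 14, wild type at LLPH (wt/wt) or homozygous for the Nterm allele (Nterm/Nterm), each with 3 RNA-seq and 3 Ribo-seq libraries. RNA-seq measures the level of each mRNA, and Ribo-seq counts footprints, the mRNA fragments covered by ribosomes. The wt/wt RNA libraries held 24998450, 21834425 and 25089790 counts and the Nterm/Nterm RNA libraries 19794346, 18944427 and 21478215. The wt/wt footprint libraries held 13155130, 16356419 and 13970957 counts and the Nterm/Nterm footprint libraries 12652833, 13125355 and 15177310. Genotypes are those of the sample titles, since the genotype tag of the 6 footprint samples names the opposite genotype. Every direction given for footprints or translational efficiency rests on the titles and descriptions, and the column names of the deposited counts name the same genotypes as these.

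LLPH, the human relative of an Aplysia factor in long-term synaptic facilitation and the gene that the genotypes name, had fewer footprints and no called change in RNA in Nterm/Nterm neurons. Its RNA counts were 676, 627 and 687 in wt/wt and 611, 603 and 630 in Nterm/Nterm libraries, or 27.8 ± 0.807 and 30.6 ± 1.14 CPM (SD, n = 3). The RNA log2 change was 0.14 ± 0.06 (SE, adjusted p = 0.135), not past the threshold for adjusted p, though the ratio of 1.10 had a counting interval of 1.04 to 1.18. Its footprint counts were 88, 135 and 98 in wt/wt and 39, 22 and 36 in Nterm/Nterm libraries, a ratio of 3.05 with a 95% counting interval of 2.42 to 3.87. The footprint log2 change was -1.60 ± 0.19 (SE, adjusted p = 1.77e-05). Since the part of LLPH altered by the allele is not given, its footprints check the titles only as far as a loss is taken to belong to Nterm/Nterm.

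The RNA comparison asked which mRNAs differ in level between Nterm/Nterm and wt/wt neurons. A few named genes were close to absent from 1 genotype: the zinc finger gene ZNF667, the clustered protocadherin PCDHA10 and the ubiquitin ligase TRIM58 were nearly lost in Nterm/Nterm, and TCEAL5, of the transcription elongation factor A-like family, was nearly lost in wt/wt. Across the transcriptome, changes were smaller. Higher in Nterm/Nterm were 34 of 56 neuronal cytoskeleton genes, 16 of 24 cholesterol synthesis genes, 29 of 68 axon guidance genes, 14 of 59 presynaptic genes and 9 of 51 postsynaptic genes. Lower were 12 of 20 mesenchymal markers, 10 of 15 interferon response genes, 17 of 30 p53 targets and 48 of 78 cytosolic ribosomal protein genes. Camera called each of these lists, and none passed with an estimated correlation (adjusted p = 0.463 or 0.486).

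ZNF667 had 357, 291 and 385 counts in wt/wt and 0, 0 and 8 in Nterm/Nterm RNA libraries, a ratio of 108 with a counting interval of 54.8 to 252 (log2 change -6.70 ± 0.37 SE, adjusted p = 7.62e-07). PCDHA10, a neuronal adhesion molecule, went from 51.7 ± 2.54 to 0.762 ± 0.135 CPM (SD, n = 3), a log2 change of -6.07 ± 0.12 (adjusted p = 1.29e-11). TRIM58 went from 17.02 ± 1.39 to 0.671 ± 0.189 CPM, a log2 change of -4.67 ± 0.17 (adjusted p = 1.29e-08). TCEAL5 went from 0.109 ± 0.0583 to 21.9 ± 2.37 CPM, a log2 change of 7.55 ± 0.22 (adjusted p = 1.33e-09). The ranking here covers only transcripts with a symbol and at least 10 CPM in the higher group. The next largest decreases were in PCDHB5, also a clustered protocadherin, at -2.33, the secreted selenium carrier SELENOP at -1.65, the growth factor IGF2 at -1.64, the collagen gene COL9A3 at -1.62, the zinc finger gene ZNF471 at -1.55, the sulfotransferase SULT1C4 at -1.44 and MXRA8 at -1.4. The next largest increases were in ARHGAP36, an inhibitor of protein kinase A, at 1.4, the neuronal adaptor SHC3 at 1.23, the GABA-A receptor subunit GABRG3 at 1.19, the zinc finger gene ZFP28 at 1.09, BRINP2 at 1.07, VWC2 at 0.88, CPNE8 at 0.86, the protocadherin PCDHGB4 at 0.85 and the neuroectoderm transcription factor SOX1 at 0.84. By the rule for naming them, the 2 genotypes did not overlap in any of these 20 genes. A transcript without a name rose by 5.985, with 3, 0 and 3 counts in wt/wt and 124, 98 and 118 in Nterm/Nterm. Others without a name changed by -5.912 and -7.566.

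The clustered protocadherins, grouped after their values were seen, moved in both directions. Of 19 tested members, 6 were higher and 5 lower in Nterm/Nterm RNA. How reads were shared out between these close paralogs is not given, and the other alpha members together gained 51.6 CPM where PCDHA10 lost 50.9 CPM.

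Of 14659 transcripts tested in RNA, 2624 passed the threshold, 1063 higher and 1561 lower in Nterm/Nterm. Of these, 140 changed by more than 2-fold, 26 higher and 114 lower, and 37 of the 140 had a name. The median size of a called change was 0.32 on the log2 scale. The 2 genotypes did not overlap for 36.2% of the transcripts, where chance gives 10%, and the first principal component, with 45% of the variance, separated them. The count of called transcripts was 841 without wt/wt RNA library 1, 964 without wt/wt RNA library 2 and 1729 without Nterm/Nterm RNA library 3.

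Camera called lists of neuronal genes higher in Nterm/Nterm RNA. Of 56 genes of the neuronal cytoskeleton, 34 were higher and 2 lower (36 and 2 adjusted over the list alone), with a median log2 change of 0.16 (camera adjusted p = 3.66e-10, adjusted p = 0.463 with an estimated correlation). Among them were the neurofilament genes NEFL (0.30 ± 0.05 SE) and NEFM (0.26 ± 0.04), the kinesin KIF21A (0.27 ± 0.04) and the microtubule-binding MAP1B (0.22 ± 0.04). Of 68 axon guidance and adhesion genes, 29 were higher and 7 lower (38 and 9 adjusted over the list alone), with a median of 0.15 (camera adjusted p = 4.69e-07, adjusted p = 0.463 with an estimated correlation). The adhesion genes TENM2 (0.60 ± 0.08) and PCDH17 (0.54 ± 0.08) rose, and the semaphorin co-receptors NRP2 (-0.65 ± 0.08) and NRP1 (-0.38 ± 0.06) fell. Of 38 voltage-gated channel genes, 13 were higher and 1 lower (14 and 1 adjusted over the list alone; median 0.14, camera adjusted p = 1.24e-05, adjusted p = 0.486 with an estimated correlation), with the calcium channel gene CACNA1B at 0.33 ± 0.06 and CACNA2D3 at -0.34 ± 0.07. Without Nterm/Nterm RNA library 3, the channel median was 0.09. In the same libraries, the markers of mesenchymal cells had a median of -0.31 and those of neural progenitors a median of -0.37.

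Synaptic genes moved in part. Of 59 presynaptic genes, 14 were higher and 3 lower (20 and 5 adjusted over the list alone), with a median of 0.12 (camera adjusted p = 4.75e-05, adjusted p = 0.486 with an estimated correlation). The vesicle calcium sensor SYT1 (0.23 ± 0.04) and SYT11 (0.21 ± 0.04) rose, while the active-zone scaffold PCLO (-0.43 ± 0.06) and the vesicle protein SV2B (-0.41 ± 0.07) fell. Of 51 postsynaptic genes, 9 were higher and 2 lower (13 and 2 adjusted over the list alone), with a median of 0.08 (camera adjusted p = 0.000944, adjusted p = 0.486 with an estimated correlation). The glutamate receptor genes GRIA3 (0.66 ± 0.10) and GRIK2 (0.64 ± 0.12) rose and the kinase gene CAMK2D (-0.35 ± 0.07) fell. Of 14 markers of peripheral sensory neurons, 6 were higher and 1 lower, counts that held when adjusted over the list alone, with a median of 0.18 (camera adjusted p = 0.000931, adjusted p = 0.463 with an estimated correlation). These included the neurotrophin receptor NTRK2 (0.36 ± 0.04), the transcription factor ISL1 (0.33 ± 0.06) and the receptor RET (0.29 ± 0.05). Without Nterm/Nterm RNA library 3, the medians were 0.08 for presynaptic genes, 0.03 for postsynaptic genes and 0.11 for the sensory markers, each still called by camera. The mesenchymal markers, at a median of -0.31, again stood beside these changes.

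Camera called the cholesterol synthesis list higher. Of 24 genes tested, 16 were higher and 0 lower (19 and 0 adjusted over the list alone), with a median of 0.21 (camera adjusted p = 1.53e-09, adjusted p = 0.463 with an estimated correlation). Examples are the sterol synthesis enzymes LSS (0.34 ± 0.05) and CYP51A1 (0.24 ± 0.04). The mesenchymal and neural progenitor markers had medians of -0.31 and -0.37 in the same libraries.

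Camera called lists of markers of other cell types lower in Nterm/Nterm RNA. Of 20 mesenchymal and fibroblast markers, 12 were lower and 1 higher (16 and 1 adjusted over the list alone), with a median of -0.31 (camera adjusted p = 5.04e-10, adjusted p = 0.463 with an estimated correlation). The collagen genes COL1A1 (-1.31 ± 0.16) and COL1A2 (-0.54 ± 0.08) and the fibrillin gene FBN1 (-0.74 ± 0.10) fell. Of 15 neural progenitor markers, 8 were lower and 2 higher (9 and 3 adjusted over the list alone), with a median of -0.37 (camera adjusted p = 0.00215, adjusted p = 0.463 with an estimated correlation). NOTCH1 (-0.55 ± 0.08), the helix-loop-helix inhibitor ID3 (-0.50 ± 0.05) and the intermediate filament gene VIM (-0.41 ± 0.05) fell, and SOX1 rose. Of 10 pluripotency markers, 3 were lower and 0 higher, also when adjusted over the list alone, with a median of -0.17 (camera adjusted p = 0.0015, adjusted p = 0.463 with an estimated correlation). They were LIN28A (-0.51 ± 0.07), SOX2 (-0.36 ± 0.08) and CDH1 (-0.35 ± 0.07). Of 13 proliferation genes, 5 were lower and 0 higher (6 and 0 adjusted over the list alone), with a median of -0.24 (camera adjusted p = 0.000274, adjusted p = 0.463 with an estimated correlation), among them HMGB2 (-0.89 ± 0.12) and TYMS (-0.52 ± 0.08). The pluripotency median was -0.27 without wt/wt RNA library 3, and the proliferation median -0.16 without wt/wt RNA library 2.

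The interferon, p53 and cytosolic ribosome lists were called lower as well. Of 15 interferon response genes, 10 were lower and 0 higher (13 and 0 adjusted over the list alone), with a median of -0.43 (camera adjusted p = 2.42e-09, adjusted p = 0.463 with an estimated correlation). They included BST2 (-0.90 ± 0.12), IFIT3 (-0.80 ± 0.13) and ISG15 (-0.41 ± 0.07). Of 30 p53 target genes, 17 were lower and 0 higher (20 and 0 adjusted over the list alone), with a median of -0.25 (camera adjusted p = 1e-09, adjusted p = 0.463 with an estimated correlation). They included GDF15 (-0.60 ± 0.10), the DNA repair gene DDB2 (-0.49 ± 0.08), FDXR (-0.46 ± 0.08) and PLK2 (-0.35 ± 0.06). Of 78 cytosolic ribosomal protein genes, 48 were lower and 0 higher (63 and 0 adjusted over the list alone), with a median of -0.16 (camera adjusted p = 4.24e-13, adjusted p = 0.486 with an estimated correlation). RPS27 (-0.27 ± 0.05), RPS15A (-0.25 ± 0.04) and RPL28 (-0.25 ± 0.05) were among them, and the median was -0.16 under each of 2 other scalings too. The mesenchymal markers had a median of -0.31 in the same libraries, with 12 of 20 called lower and 1 higher.

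**Figure D1:**
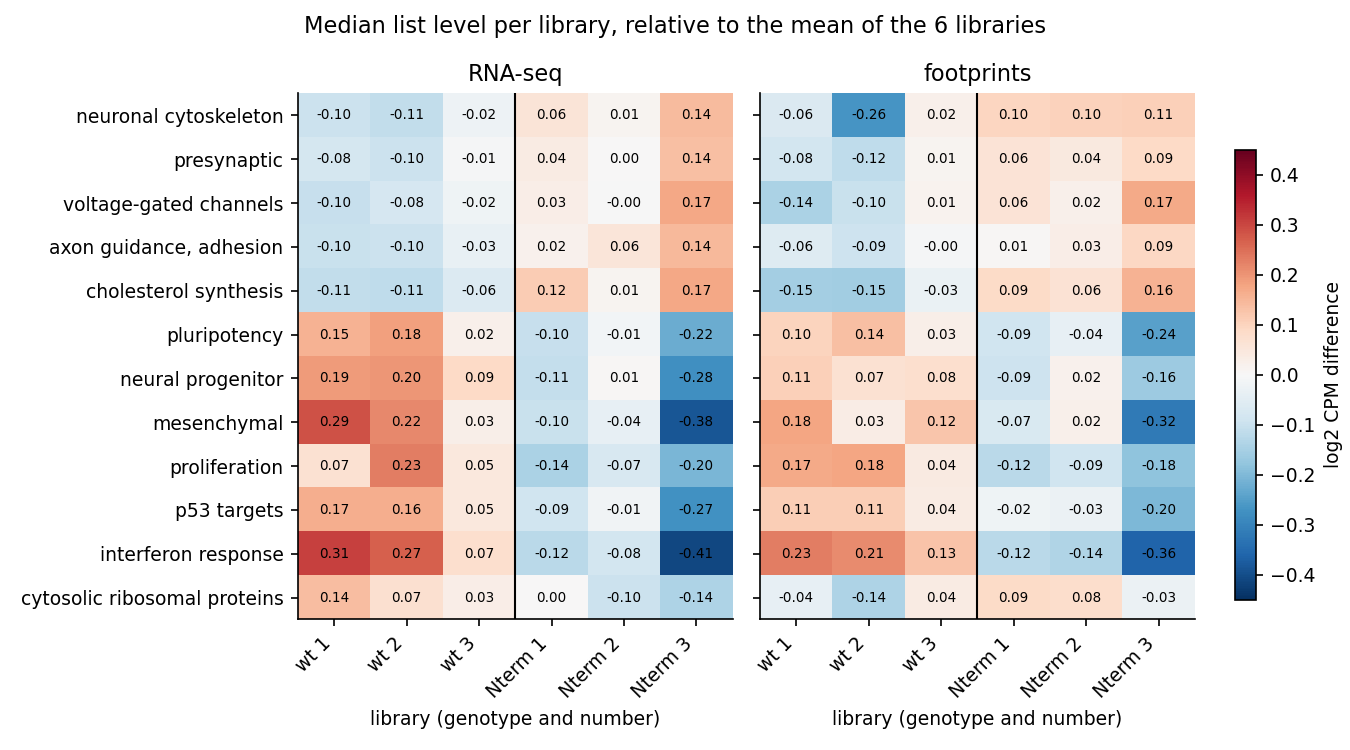
Median level of 12 gene lists in each of the 12 libraries, as the log2 CPM difference from the mean of the 6 libraries of an assay, with RNA-seq on the left and footprints on the right. Nterm/Nterm library 3 lies farthest from the mean for most lists in RNA, with the interferon list at -0.41, while wt/wt library 3 and Nterm/Nterm library 2 lie close to it, at 0.07 and -0.08.

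The libraries of 1 genotype differed along the same lists. The neuronal cytoskeleton list stood at 0.14 in Nterm/Nterm RNA library 3 and at 0.01 in library 2, and at -0.10, -0.11 and -0.02 in the wt/wt libraries. The mesenchymal list stood at -0.38 in Nterm/Nterm RNA library 3 and -0.04 in library 2, and at 0.29, 0.22 and 0.03 in the wt/wt libraries.

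The footprint comparison asked which mRNAs carry more or fewer ribosomes in Nterm/Nterm neurons. The same single genes stood out: ZNF667, PCDHA10, TRIM58 and PCDHB5 had almost no footprints in Nterm/Nterm, and TCEAL5 had almost none in wt/wt. Fewer footprints were found for 9 of 20 mesenchymal markers and 9 of 14 interferon response genes, and more for 9 of 24 cholesterol synthesis genes, 7 of 56 neuronal cytoskeleton genes and 14 of 68 axon guidance genes. Camera called each of these lists, and none passed with an estimated correlation (adjusted p = 0.506). Of the 78 ribosomal protein genes, 48 were lower in RNA, and 0 were called lower in footprints by edgeR, DESeq2 or limma-voom (0 at an unadjusted p under 0.05).

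ZNF667 had 231, 282 and 214 footprints in wt/wt and 0, 2 and 1 in Nterm/Nterm libraries, a ratio of 223 with a counting interval of 76.1 to 1090. TRIM58 had 102, 183 and 152 against 0, 0 and 3, a ratio of 134 with an interval of 45.7 to 654. PCDHA10 fell by 6.78 on the log2 scale (SE 0.15, adjusted p = 2.71e-17), and PCDHB5 went from 25.1 ± 1.26 to 0.406 ± 0.212 CPM (SD, n = 3), a log2 change of -5.96 ± 0.21 (adjusted p = 4.79e-14). TCEAL5 rose by 6.80 ± 0.24 (adjusted p = 4.79e-14). A transcript without a name rose by 5.77, with 4, 8 and 4 footprints in wt/wt and 266, 278 and 276 in Nterm/Nterm. Others without a name changed by 5.142 and -4.946, and the ranking here covers only transcripts with a symbol. The other large decreases were in SELENOP at -1.84, COL9A3 at -1.67, the interferon-induced GTPase GBP2 at -1.42, SULT1C4 at -1.32, the succinate dehydrogenase assembly factor SDHAF4 at -1.23, the collagen gene COL22A1 at -1.21 and the matrix gene FBLN2 at -1.21. The other large increases were in ARHGAP36 at 1.41, ZFP28 at 0.99, the neuropeptide receptor PRLHR at 0.91, PCDHGB4 at 0.88, BRINP2 at 0.80, GABRG3 at 0.79, FAM13B at 0.78, the protocadherin PCDHB10 at 0.74 and VWC2 at 0.74. VWC2 lost its call without wt/wt footprint library 1 (adjusted p = 0.0575, the highest of 6 fits that each left out 1 library). Among the 19 clustered protocadherins, 8 were higher and 5 lower, and the other beta members together gained 45.2 CPM where PCDHB5 lost 24.7 CPM, so shared reads leave these values uncertain.

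Of 13566 transcripts tested in footprints, 1800 passed, 591 higher and 1209 lower in Nterm/Nterm. Of these, 150 changed by more than 2-fold, 19 higher and 131 lower. The genotypes did not overlap for 30.7% of the transcripts, where chance gives 10%, and the first principal component, with 58.2% of the variance, separated them. The count was 954 without wt/wt footprint library 1, 978 without wt/wt library 2 and 965 without Nterm/Nterm library 3. With the genotype tag in place of the titles, each of these changes has the opposite sign.

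Camera called lists of neuronal and cholesterol synthesis genes higher in footprints, while most members did not pass on their own. Of 56 neuronal cytoskeleton genes, 7 were higher and 0 lower (23 and 0 adjusted over the list alone), with a median log2 change of 0.20 (camera adjusted p = 2.56e-09, adjusted p = 0.506 with an estimated correlation). NEFM (0.39 ± 0.10 SE) and NEFL (0.34 ± 0.09) rose, but each lost its call in 3 of 6 fits that left out 1 library: those without wt/wt library 1, Nterm/Nterm library 1 or Nterm/Nterm library 2 (highest adjusted p 0.0776 and 0.0898). In wt/wt footprint library 2 this list stood at -0.26, lower than in the other libraries, and without that library its median was 0.12 and that of the axon guidance list below 0.07. Of 24 cholesterol synthesis genes, 9 were higher and 0 lower (19 and 0 adjusted over the list alone), with a median of 0.21 (camera adjusted p = 5.36e-08, adjusted p = 0.506 with an estimated correlation), among them DHCR7 (0.38 ± 0.07) and SQLE (0.29 ± 0.07). Of 68 axon guidance and adhesion genes, 14 were higher and 5 lower (21 and 9 adjusted over the list alone; median 0.10, camera adjusted p = 0.00101, adjusted p = 0.506 with an estimated correlation), with TENM2 at 0.63 ± 0.09 and the ephrin receptor EPHA4 at 0.62 ± 0.10 up and NRP2 at -0.58 ± 0.07 down. Of 38 voltage-gated channel genes, 7 were higher and 2 lower (13 and 2 adjusted over the list alone; median 0.17, camera adjusted p = 0.000139, adjusted p = 0.506 with an estimated correlation). The mesenchymal markers had a median of -0.16 in these libraries.

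Camera called the mesenchymal and interferon lists lower in footprints. Of 20 mesenchymal markers, 9 were lower and 0 higher (9 and 1 adjusted over the list alone), with a median of -0.16 and a mean of -0.31 (camera adjusted p = 1.33e-06, adjusted p = 0.506 with an estimated correlation). COL1A1 (-1.13 ± 0.13), FBN1 (-0.92 ± 0.10), COL6A2 (-0.90 ± 0.11) and COL5A1 (-0.67 ± 0.10) fell. The mesenchymal median was -0.06 without Nterm/Nterm footprint library 3 and -0.24 without wt/wt or Nterm/Nterm library 2. Of 14 interferon response genes, 9 were lower and 0 higher (12 and 1 adjusted over the list alone), with a median of -0.35 (camera adjusted p = 2.56e-09, adjusted p = 0.506 with an estimated correlation), among them IFI27 (-0.94 ± 0.12), IFIT3 (-0.86 ± 0.11), BST2 (-0.72 ± 0.10) and MX1 (-0.58 ± 0.10). Of 21 immediate early genes, 5 were lower and 2 higher, also when adjusted over the list alone, with a median of -0.10 (camera adjusted p = 0.0272, adjusted p = 0.605 with an estimated correlation). FOS (-0.85 ± 0.11), EGR1 (-0.77 ± 0.09) and CCN2 (-0.49 ± 0.09) fell and MYC (0.28 ± 0.07) rose. This list lost its camera call without wt/wt library 2 (adjusted p = 0.122) or 3 (0.0951) or Nterm/Nterm library 3 (0.18, median -0.02). Of 10 pluripotency markers, 3 were lower and 0 higher (5 and 0 adjusted over the list alone; median -0.24, camera adjusted p = 0.00183, adjusted p = 0.506 with an estimated correlation), with LIN28A at -0.45 ± 0.07. Of 15 neural progenitor markers, 6 were lower and 2 higher (7 and 2 adjusted over the list alone), and the list, at a median of -0.12, was not called (camera adjusted p = 0.0783). Without Nterm/Nterm footprint library 2 it was called (camera adjusted p = 0.0228, adjusted p = 0.552 with an estimated correlation, median -0.17).

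Ribosomal protein genes had a median log2 change of 0.10 in footprints (camera adjusted p = 6.6e-05, adjusted p = 0.605 with an estimated correlation), and of 0.045 without wt/wt library 2 (camera adjusted p = 0.0223). With edgeR, 0 of the 78 genes passed either over all genes or adjusted over the list alone, 12 had an unadjusted p under 0.05, all higher, and DESeq2 and limma-voom called 0. RPL32 had a log2 change of 0.20 ± 0.08 (adjusted p = 0.0863) and FAU one of 0.18 ± 0.07 (adjusted p = 0.121).

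RNA and footprint changes were set side by side to ask whether ribosome occupancy followed the mRNA level. Among genes near 0 in 1 genotype, ZNF667, PCDHA10, TRIM58 and TCEAL5 changed in the same direction in both. Across 13422 transcripts tested in both, the log2 changes correlated with Pearson r = 0.791 and Spearman rho = 0.681, across genes, which are not independent replicates. Without transcripts over 16-fold apart, Pearson r was 0.743. Of the transcripts called in RNA, 94.6% had the same sign in footprints. A total of 348 were called higher in both, where 44.9 would be shared by chance, and 832 lower in both, where 135 would be. Opposite calls were made for 2 genes: PCDHB9, with RNA at -0.29 (adjusted p = 0.0135) and footprints at 0.69 (adjusted p = 0.00207), and the proteoglycan gene CSPG4, with RNA at 0.35 (adjusted p = 0.0441) and footprints at -0.66 (adjusted p = 0.0093). The RNA call of CSPG4 was lost without wt/wt RNA library 1 or 2 or Nterm/Nterm RNA library 1 or 3 (highest adjusted p 0.179). With the genotype tag in place of the titles, r was -0.791.

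**Figure D2:**
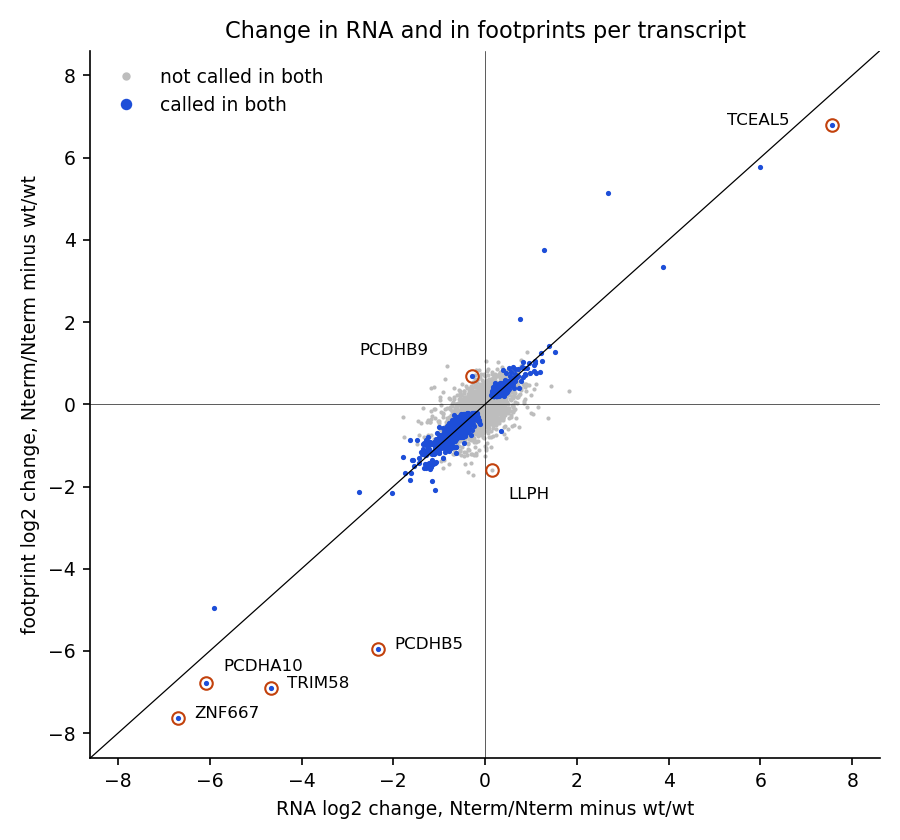
Log2 change between Nterm/Nterm and wt/wt in RNA (horizontal axis) and in footprints (vertical axis) for each transcript tested in both, with transcripts called in both in blue, genes named in the text circled and the diagonal marking equal change. Most points lie near the diagonal (r = 0.791), with LLPH at 0.14 in RNA and -1.60 in footprints, and PCDHB5 at -2.33 and -5.96.

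The comparison of translational efficiency asked which mRNAs carry more or fewer ribosomes than their RNA level gives, relative to other mRNAs. Scaling within each assay set the median change near 0 (0.013), so a change in translation shared by all mRNAs could not be seen. LLPH itself and the protocadherin PCDHB5 had fewer footprints per mRNA in Nterm/Nterm, and the protocadherin PCDHB9 had more. Camera called the ribosomal protein list higher, with a median of 0.26 (adjusted p = 0.437 with an estimated correlation). Of its 78 genes, edgeR without a block and limma-voom called 0, with 65 at an unadjusted p under 0.05, and DESeq2 called 27, or 2 without its filter on the mean count.

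LLPH had a log2 change in translational efficiency of -1.74 ± 0.18 (SE, n = 3 per group, adjusted p = 6.67e-05), a ratio of 0.299 between the genotypes. The part of LLPH altered by the allele is not given, so this ratio cannot be read as a change in translation alone. PCDHB5 changed by -3.63 ± 0.37 (adjusted p = 6.67e-05), with RNA at 13.1 ± 1.37 CPM in wt/wt and 2.60 ± 0.809 in Nterm/Nterm (SD, n = 3). For translational efficiency, though not for RNA or footprints, it lies outside the rule for named genes, with a mean RNA level under 10 CPM, and was chosen after its values were seen. PCDHB9 changed by 0.98 ± 0.15 (adjusted p = 0.00905) and lost its call without wt/wt footprint library 1 or 2 (highest adjusted p 0.0779 over 12 fits). CSPG4, at -1.01, did not pass with edgeR without a block (adjusted p = 0.105) and passed with DESeq2 without its filter on the mean count (adjusted p = 0.0201). It also passed with the edgeR block for genotype and number (adjusted p = 0.00466). Shared reads leave the protocadherin values uncertain.

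Of 14786 transcripts tested for translational efficiency, 3 passed with edgeR without a block, 1 higher and 2 lower, and 680 had an unadjusted p under 0.05, which is 4.6%. With footprint and RNA libraries paired by number, which the labels do not state as a pairing, the genotypes did not overlap for 13.4% of the transcripts, where chance gives 10%. DESeq2 called 38 genes, all higher in Nterm/Nterm and none of them among these 3, since its filter on the mean count gave no adjusted p to 14046 transcripts. Without that filter, a setting added after seeing the data, it called 8, the same 3 included. With a block for libraries of 1 genotype and number, edgeR called 20, 16 higher and 4 lower, again with the same 3 included.

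**Figure D3:**
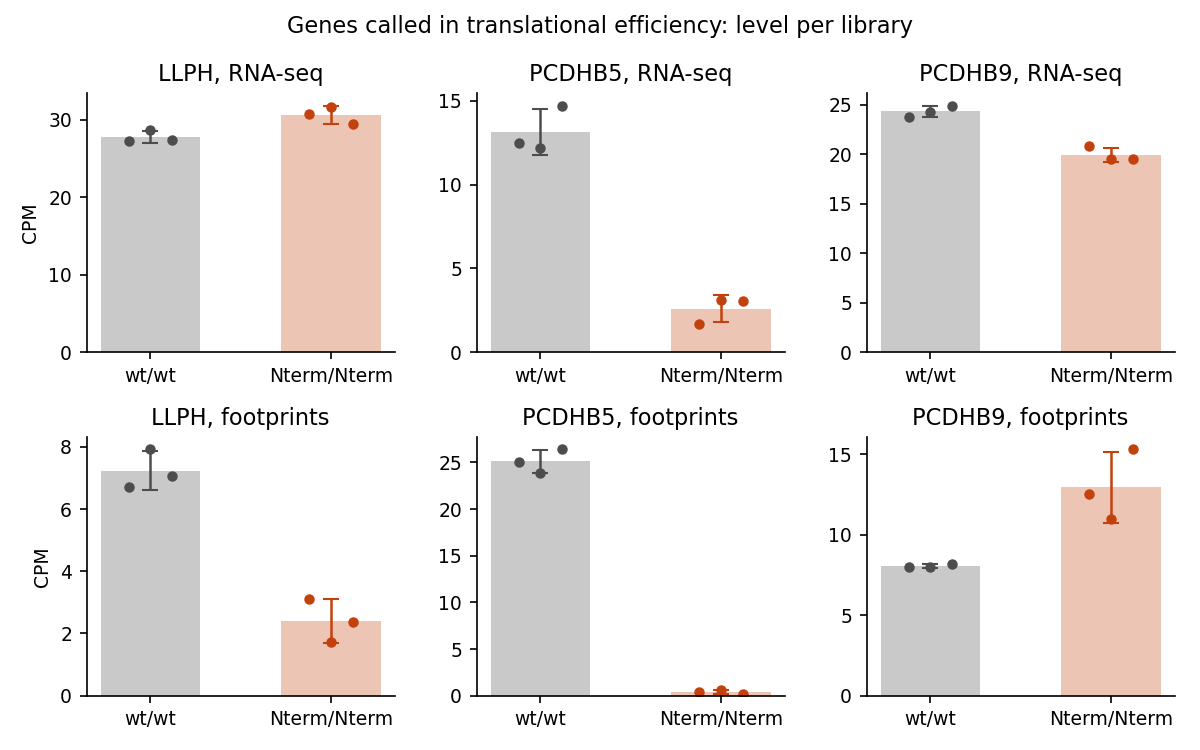
CPM of LLPH, PCDHB5 and PCDHB9 in RNA-seq (top) and footprints (bottom), with bars for the mean, error bars for the SD and a point for each of 3 libraries per genotype. LLPH footprints average 7.24 CPM in wt/wt and 2.4 CPM in Nterm/Nterm, while its RNA averages 27.8 and 30.6 CPM.

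Ribosomal protein genes had a median log2 change in translational efficiency of 0.26, with all 78 members above 0 (camera adjusted p = 1.09e-68, adjusted p = 0.437 with an estimated correlation). With edgeR without a block, 0 passed over all genes and 63 passed adjusted over the list alone, 65 had an unadjusted p under 0.05, and limma-voom called 0. The 38 calls of DESeq2 held 27 ribosomal protein genes, such as RPL7A, RPL5 and RPL28. In edgeR without a block, RPL28 changed by 0.36 (adjusted p = 0.616) and RPS15A by 0.35 (adjusted p = 0.304). With the block for genotype and number, both passed (adjusted p = 0.0312 and 0.0207). Of 48 translation factors, 0 passed with edgeR without a block and 3 passed adjusted over the list alone, with a median of 0.09 (camera adjusted p = 3.45e-06, adjusted p = 0.767 with an estimated correlation), and the elongation factor EEF2 was at 0.34 (adjusted p = 0.765). DESeq2 called 3 translation factors, EEF2 among them (adjusted p = 0.0156), but EEF2 was not among its 8 calls without the filter on the mean count. The nuclear genes of oxidative phosphorylation had a median of 0.11 (camera adjusted p = 4.57e-09, adjusted p = 0.767 with an estimated correlation) and glycolysis genes 0.10 (camera adjusted p = 9.65e-05, adjusted p = 0.767 with an estimated correlation). Wt/wt footprint library 2 stood lowest for ribosomal proteins, at -0.14, and without it the medians were 0.06 for translation factors and 0.07 for oxidative phosphorylation.

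The other 7 lists that camera called in translational efficiency depended on single libraries. Over 12 fits that each left out 1 library, the call was lost in 7 for mesenchymal markers (median 0.11), in 5 each for p53 targets (0.08), axon guidance (-0.02) and neuronal cytoskeleton (0.05), in 2 for the unfolded protein response (0.09) and in 1 each for heat shock genes (0.07) and the proteasome (0.06). Without Nterm/Nterm RNA library 3, the medians were 0.03 for mesenchymal markers (adjusted p = 0.791), 0.02 for p53 targets (0.575) and -0.005 for axon guidance (0.575), and the unfolded protein list had an adjusted p of 0.124. Without wt/wt footprint library 2, they were 0.01 for heat shock genes (0.413), 0.04 for the proteasome (0.0826) and -0.03 for the neuronal cytoskeleton (0.0779). With an estimated correlation the 7 lists had adjusted p-values from 0.807 to 0.993.

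**Figure D4:**
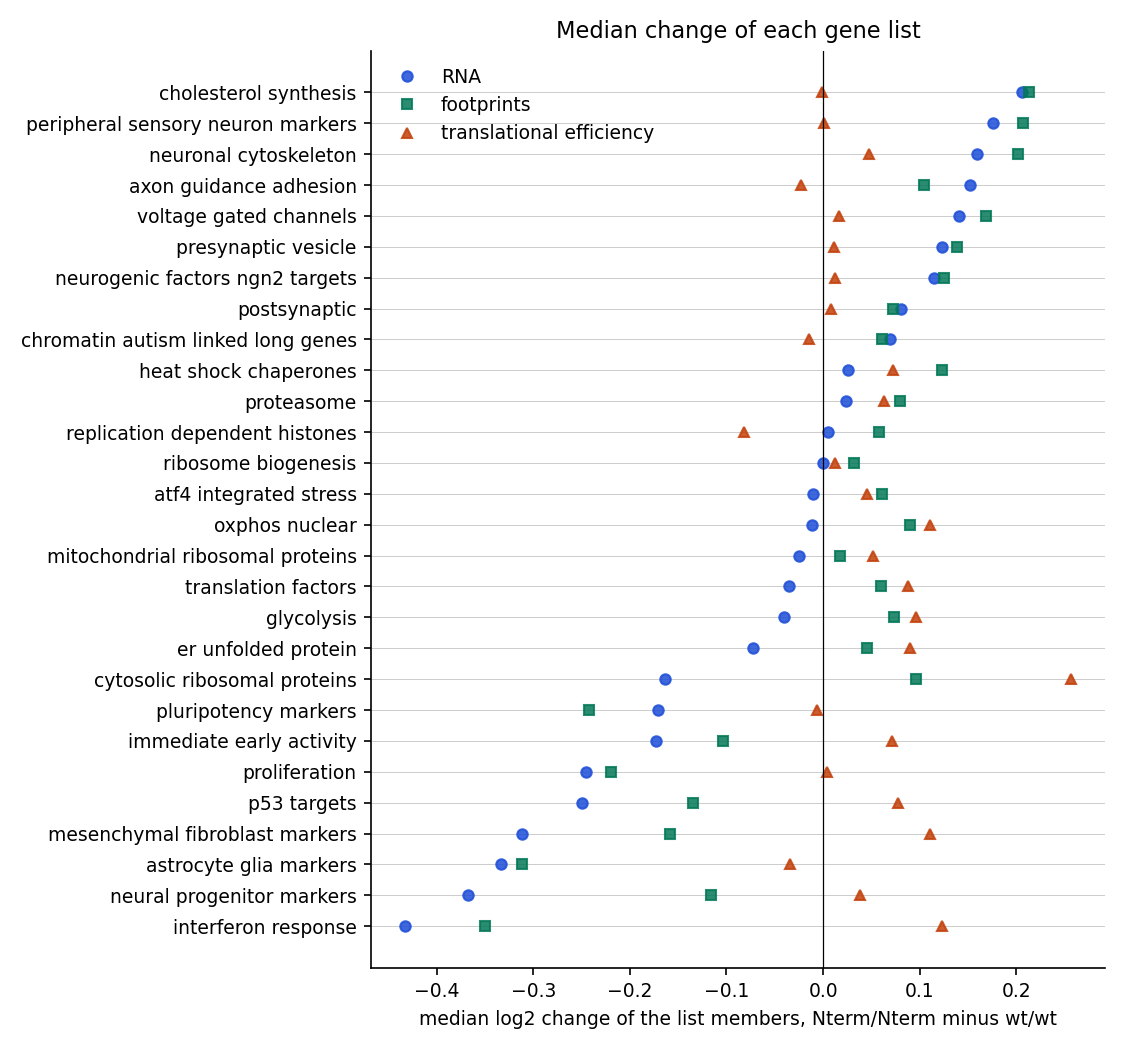
Median log2 change of the members of each of 28 gene lists in RNA (circles), footprints (squares) and translational efficiency (triangles). The cytosolic ribosomal proteins lie at -0.16 in RNA, 0.10 in footprints and 0.26 in translational efficiency, and the neural progenitor markers at -0.37, -0.12 and 0.04.

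Over all 28 lists, camera called 18 in RNA, 9 higher and 9 lower, 20 in footprints, 13 higher and 7 lower, and 11 in translational efficiency, 10 higher and 1 lower. The last count was 7 without wt/wt RNA library 1 or without Nterm/Nterm RNA library 3. With an estimated correlation the lowest adjusted p was 0.463 in RNA, 0.506 in footprints and 0.437 in translational efficiency, so no list kept its call. With fry, which asks whether a list moves 1 way on balance, the lowest adjusted p was 0.0629, 0.0804 and 0.347, and 16, 11 and 2 lists had an unadjusted p under 0.05.

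The deposited translational efficiency table compares the same groups. Its lowest p was that of PCDHB5, with mean ratios of 0.174 ± 0.0914 in Nterm/Nterm and 1.85 ± 0.108 in wt/wt (SD, 3 libraries each). LLPH had 0.0763 ± 0.0227 and 0.252 ± 0.0156, and the fourth lowest p. PCDHB9 had 0.622 ± 0.117 and 0.321 ± 0.00449, and rank 475. Of 10932 transcripts listed, 511 had a deposited p under 0.05, 258 higher and 253 lower in Nterm/Nterm, where 547 would be so by chance. After Benjamini-Hochberg adjustment, 0 passed, with a lowest adjusted p of 0.443. Of the listed transcripts, 516 had an unadjusted p under 0.05 in the edgeR fit, and 212 had one in both. Both p-values come from the same 12 libraries, so this overlap is no independent support for either. Across genes, the deposited log2 ratio and the fitted log2 change correlated with Pearson r = 0.908 and Spearman rho = 0.992. Whether changes in translational efficiency follow coding sequence length was not analysed here.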

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

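The tests of mislabelling, shared reads, variation within genotypes, a share of 1 kind of cell, 1 footprint library and short mRNAs were chosen after the result was seen, and the bounds for 1 kind of cell and for 1 footprint library were revised after it, while those of depth and mRNA abundance were set before. For 3 genes the change between genotypes differed between footprints and RNA, by a test of the interaction itself. The difference was -3.63 on the log2 scale for PCDHB5 (adjusted p = 6.67e-05), -1.74 for LLPH (adjusted p = 6.67e-05) and 0.98 for PCDHB9 (adjusted p = 0.00905). For LLPH, what the allele changes is not given, so its difference cannot be read as a change in translation alone. The fits without wt/wt footprint library 1 or 2 did not call PCDHB9 (highest adjusted p 0.0779).

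The first pattern is single genes near 0 in 1 genotype, such as ZNF667, TRIM58, PCDHA10, PCDHB5 and TCEAL5. Mislabelled footprint libraries would give RNA and footprints opposite signs, and 8 of the 8 transcripts over 16-fold apart and tested in both had the same sign, which argues against the genotype tag. Shared reads stay open for the protocadherins, since the other beta members gained 183% (SE 65.7) of what PCDHB5 lost, and the other alpha members 83.3% (SE 26.4) of what PCDHA10 lost, each in the assay with the lower share. A switch of expression between cluster members could give the same sums, so the values do not part the explanations. The genotype, and a difference between clones that the design ties to it, stay open and untested.

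The second pattern is neuronal lists higher and non-neuronal lists lower in Nterm/Nterm. For a library-depth difference, every RNA library was thinned to the lowest total, and the mesenchymal median was -0.314 after and -0.312 before. Thinning keeps the expected ratio of a well-covered gene, so this median could hardly have moved. No conclusion on depth is drawn from it. Variation between libraries of 1 genotype, whose source is not given, may contribute. The main component of footprint variation within genotypes correlated with the RNA change between genotypes (0.418 in size, across genes). A lower share of mesenchymal cells, which cytosine arabinoside would reduce, stays open: the members spread by more than their errors (I2 of 92.6%), but a member also transcribed in neurons would fall by less, only THY1 was called higher (not without wt/wt RNA library 1 or 2 or Nterm/Nterm RNA library 1 or 3, highest adjusted p 0.172), and the most abundant, FN1, went from 2023 to 1353 CPM. Of this list, 0 members are in another list and 19 of the 20 tested had 10 CPM or more in Nterm/Nterm, and the genotype stays open and untested.

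The third pattern is the higher translational efficiency of ribosomal protein genes. A trend with mRNA abundance as the whole cause is argued against, since 10000 random lists matched on RNA level centred on 0.06, against 0.257. Abundance may give a part, since all transcripts had a median of 0.013. Of the random lists, 100% had a lower median, the highest at 0.103. Their genes were drawn singly, while the correlation within the ribosomal protein list was estimated at 0.768, so their spread is too narrow. Wt/wt footprint library 2 as the whole cause is argued against, since the median without it was 0.207. A different yield of short mRNAs could contribute, since oxidative phosphorylation genes, also short, had a median of 0.111, and coding lengths were not used here. Mitochondrial ribosomal proteins and replication-dependent histones had medians of 0.052 and -0.082, and camera called neither list (adjusted p = 0.128 and 0.172). Shared reads with pseudogenes and the genotype stay open and untested.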

How the results depend on the processing

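Added after seeing the data were the fits without the libraries numbered 3, those of DESeq2 without its filter on the mean, and the block fit without the wt/wt libraries numbered 2. Under other scalings, filters and tools, the RNA count lay between 2446 and 2779 (main 2624), the footprint count between 1472 and 2295 (main 1800), and no gene followed singly changed direction in RNA or footprints. Of 105 called genes followed in RNA, 104 kept their call under these settings (all but CSPG4, with limma-voom), and of 66 followed in footprints, 66 did. Leaving out 1 library at a time gave 841 to 2851 calls in RNA and 954 to 2045 in footprints, the lowest without wt/wt library 1 in each. Fewer libraries were then fitted, 20 of the 105 genes in RNA and 10 of the 66 in footprints lost their call in at least 1 such fit, and 752 of the 2624 and 672 of the 1800 transcripts were called in every fit. Without the libraries numbered 3, the counts were 2677 and 1268, and 3 for translational efficiency.

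Residual correlations of libraries of the 2 genotypes with the same number were low, 0.086 to 0.103 in RNA and 0.041 to 0.223 in footprints, but exceeded those with other numbers for 3 of 3 numbers in RNA and 2 of 3 in footprints. For footprints against RNA of the same genotype and number, they were 0.117, 0.233 and 0.334 in Nterm/Nterm and 0.041, 0.081 and 0.18 in wt/wt, the highest for 5 of 6. This is a hint from the data, not the design. Since 1 or more of each set of 3 lay under 0.1, apart from that of Nterm/Nterm, the main fits have no block. That bound does not exclude a pairing, and the counts of calls depend on it. Overlap of the genotypes in translational efficiency was judged on libraries paired by number all the same. With a replicate block, 4504 genes were called in RNA, 2317 in footprints and 5 in translational efficiency, and with a block for genotype and number, 20 in translational efficiency, with CSPG4 and the ribosomal protein genes RPS15A, RPL28, RPL36 and RPL32 (RPL36 chosen after its values were seen) among them, or 41 without the wt/wt footprint and RNA libraries numbered 2. The cause was not tested. For translational efficiency, leaving out 1 library gave 2 to 4 calls. DESeq2 gave 38 calls, since its filter left 14046 transcripts without an adjusted p, and 8 without that filter.

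With footprint groups by the genotype tag, signs turn by construction: 1800 footprint calls were 1209 higher and 591 lower, LLPH rose by 1.60 in footprints and 1.46 in translational efficiency, PCDHB5 by 8.30 and PCDHB9 fell by 0.40, 4150 genes were called in translational efficiency, and the correlation of RNA with footprint changes was -0.791. That correlation was otherwise 0.725 to 0.789 without 1 library and 0.772 with at least 10 counts in every library.

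Camera with an estimated correlation called 0 lists in RNA, 0 in footprints and 0 in translational efficiency (0, 1 and 1 at an unadjusted p under 0.05), and 0, 0 and 0 with the replicate block as well, against 19, 20 and 13 with the block and the preset correlation, which added glial markers in RNA (adjusted p = 0.0211) and immediate early genes and ATF4 targets in translational efficiency (0.0353 each). The correlation within lists in RNA was estimated at -0.165 for glial markers up to 0.811 for p53 targets, so members of some lists are far from independent. Leaving out 1 library gave 18 lists in RNA throughout, 17 to 21 in footprints and 7 to 14 in translational efficiency, with 7 without wt/wt RNA library 1 or Nterm/Nterm RNA library 3. Adjustment of the deposited p-values left 0 of 511 transcripts. The 7 alternatives for coding sequence length were not run, and other pseudocounts do not apply to counts. Depth limits genes with few counts, such as LLPH with 22 to 135 footprints per library.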

Other observations

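The splits for translational efficiency were chosen before their result was seen, and the test of gene families and the splits for RNA and footprints were chosen after. Camera called 4 further lists in RNA. Of 37 long genes of chromatin regulation and autism, 7 were higher and 0 lower (9 and 0 adjusted over the list alone), with a median log2 change of 0.07, or 0.035 without Nterm/Nterm RNA library 3 (camera adjusted p = 0.00173, adjusted p = 0.463 with an estimated correlation). Of 32 neurogenic factors and Ngn2 targets, 7 were higher and 2 lower (15 and 2 adjusted over the list alone; median 0.12, camera adjusted p = 0.000503, adjusted p = 0.486 with an estimated correlation), with CUX2 at 0.33, ELAVL2 at 0.28 and NEUROD1, a factor of early neurons, at -0.70. Of 21 immediate early genes, 6 were lower and 1 higher (10 and 1 adjusted over the list alone; median -0.17, camera adjusted p = 0.0013, adjusted p = 0.463 with an estimated correlation), with CCN2 at -0.59 and JUNB at -0.47. Of 25 genes of the unfolded protein response, 5 were lower and 0 higher, also adjusted over the list alone (median -0.07, camera adjusted p = 0.0135, adjusted p = 0.594 with an estimated correlation), with CREB3L2 at -0.51. In the same RNA libraries, mesenchymal and neural progenitor markers had medians of -0.31 and -0.37.

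The remaining lists did not pass in RNA without a block. Of 5 tested glial markers, 3 were lower, among them CLU at -0.50, and 1 higher (median -0.33, camera adjusted p = 0.148). With the replicate block, camera called the glial list (adjusted p = 0.0211, adjusted p = 0.302 with an estimated correlation). Of 34 targets of the stress factor ATF4, 4 were higher and 3 lower (median -0.01, camera adjusted p = 0.718, with a direction opposite to the median), with CHAC1 at 0.45 and DDIT4 at -0.44. Of 24 heat shock genes, 3 were higher and 3 lower (median 0.03, camera adjusted p = 0.314), with HSPB1 at -0.64. Of 19 glycolysis genes, 0 were higher and 5 lower (median -0.04, camera adjusted p = 0.167), with HK2 at -0.54. Of 48 translation factors, 3 were higher and 7 lower (median -0.04, camera adjusted p = 0.406). Camera adjusted p was 0.718 for mitochondrial ribosomal proteins (median -0.03), 0.5 for ribosome biogenesis (median 0), 0.999 for oxidative phosphorylation (median -0.01), 0.431 for the proteasome (median 0.02) and 0.724 for replication-dependent histones (median 0.01).

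A hypothesis is that the largest changes favour gene families whose members may vary between clones, namely zinc finger and clustered protocadherin genes. The families were picked from these same changes, so their odds ratio of 4.85 among RNA calls over 2-fold is no test of it, and it stays open.

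Other splits of the libraries gave few calls. For RNA, 1 of the 10 splits of 6 libraries, the real one, gave as many as 2624 calls, and the highest other gave 1. For footprints, 1 of 10, the real one, gave as many as 1800, and the highest other gave 0. With 10 splits the share cannot fall under 0.05. For translational efficiency, 1 of 50 drawn splits, the real one, gave 3 calls or more, and the highest other gave 1. Each other drawn split mixes genotypes within an assay, which adds the difference between genotypes to the spread, so this comparison does not exclude chance. A split outside those drawn, with the footprint genotypes exchanged as in the genotype tag, gave 4150 calls, where the interaction becomes the sum of 2 changes that mostly share their sign (r = 0.791).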
